A study of Mus musculus with 24 samples.

How the data were processed

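Total RNA of bone marrow mononuclear cells was prepared with a column kit for small inputs and made into libraries with a SMART-Seq full-length cDNA kit for low input followed by Nextera XT tagmentation, per the labels. This preparation does not mark strand, so reads from a gene and its antisense partner cannot be told apart, and the strand setting of the counting is not given in the sources used here. Reads were aligned with STAR and counted per gene with featureCounts on the mm10 mouse genome, per the labels, and versions and settings are not given in the sources used here. The deposited values are whole-number counts per gene, with the gene length in bases beside them. The table has 1 count column for each of the 12 specimens while 24 samples are listed, so the 2 samples of a specimen appear only as 1 column here. It holds 24421 gene symbols, 95.7% of them in the reference symbol table, and 6573 genes had no count in any specimen. Mitochondrially encoded genes are not in the table, so that list could not be scored.

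Specimens were grouped by the treatment in the labels, with the specimen number from the title. The titles carry a date, with day 24 of a month for 11 specimens and day 30 of the same month for BTK inhibitor replicate 6. The labels do not state what was done on that date, so a batch is possible for this specimen. Counts between specimens of a group differed by far more than sampling noise (chi-square per degree of freedom from 20.5 to 633), so all 12 were kept as separate specimens. No per-sample column was left unused.

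Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr by group (smallest count 10, total count 15), leaving 12742 genes, and libraries were scaled by TMM. A group-means model over all 12 specimens was fitted with glmQLFit and tested with glmQLFTest, both robust, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. There were 8 comparisons: 6 between pairs of groups, the interaction of the inhibitors, and any difference among the 4 groups. Standard errors of log2 fold changes were taken from the F statistic. CPM values are scaled to the summed counts of the tested genes with TMM factors, and log2 CPM used a prior count of 2.

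Gene lists were fixed before the data were examined: 16 of cell type markers, 17 of pathways and 2 of sample quality. The 34 lists with at least 5 tested members were tested with limma camera on log2 CPM with a preset correlation of 0.01 between genes, adjusted over the 34 lists of a comparison. List members were also counted after adjustment over the list alone. With an estimated correlation no list was called in any of the 5 comparisons tested, and fry called 6 lists between the PI3K inhibitor and vehicle and 0 in the other 4. In each of these 5 comparisons, the highest list count from groupings that mixed the compared groups was above the real one.

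Genes named in the text followed a rule set before the data were examined. It took up to 10 genes in each direction with the largest fold change among those past the threshold, with a mean log2 CPM of at least 2 and no overlap between the 3 specimens of either group, leaving out predicted genes and antigen receptor segments, and without the overlap condition for the interaction. No overlap occurs by chance for 10% of unchanged genes in 3 against 3 specimens. Where fewer than 5 genes passed, the 5 genes per direction with the smallest p were taken, and each list gave up to 4 passing members or 2 with the smallest p. Btk, Pik3cd and Ptpn11 were always included, and Xist and Y-linked genes served as a specimen check. A fold against a group with no count used a floor of 3 counts over the group, which covers counting error only.

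Alternatives were DESeq2 1.42.0, limma voom with quality weights, other scaling factors, other filters, leaving out 10 hemoglobin genes (the planned immunoglobulin segments and mitochondrial genes are not in the table), fitting only the groups compared, and leaving out each specimen. After the data were seen, a gene length offset (a natural spline with 5 degrees of freedom per library), the same without BTK inhibitor replicate 5, Rn45s left out, and Y-linked presence as a covariate were added. The tests were tried on simulated counts with 200 genes changed. For the PI3K inhibitor against vehicle over 12613 genes, 12% of genes changed 2-fold and 76% of those changed 4-fold were recovered with 7 false calls. With a length trend between specimens added to the simulation, over 12612 genes, these shares were 4% and 47% without the length offset and 6% and 73% with it, both with 0 false calls. The added slopes were the same in each group, unlike those of the data. These false calls therefore do not cover a length trend that differs between groups. For the combination against vehicle over 12598 genes the shares were 8% and 83% with 2 false calls, and for the BTK inhibitor against vehicle over 12613 genes 8% and 78% with 3 false calls. Exact permutation tests of 3 against 3 specimens cannot go below p = 0.1 and were not used for single genes.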

Results

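Gene expression was measured by RNA-seq in bone marrow mononuclear cells of mice that carry Shp2 E76K, an activating change in the phosphatase encoded by Ptpn11 and a model of juvenile myelomonocytic leukemia. Mice received vehicle, ACP196 (an inhibitor of Bruton's tyrosine kinase, BTK), ACP319 (an inhibitor of the delta isoform of phosphoinositide 3-kinase, PI3K), or both inhibitors, for 3 weeks. The 24 deposited samples carry 12 specimen numbers, each on 2 samples. The count table holds 1 column per specimen, and each of the 4 groups has 3 specimens. Specimens are named by these numbers as replicates: 1 to 3 for vehicle, 4 to 6 for the BTK inhibitor, 7 to 9 for the PI3K inhibitor and 10 to 12 for the combination. The labels say that mice were treated and do not say that each number is a separate mouse, so p-values measure the spread between these specimens. Total counts lay between 8993950 and 22154833 per specimen, and 12742 of 24421 genes were tested.

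BTK inhibitor replicate 5 stood apart from the other libraries. It had 8993950 counts, 13560 genes with a count and 15.4% of its counts on the ribosomal RNA precursor Rn45s, against 0.203% to 0.773% in the other 11 specimens. BTK inhibitor replicate 6 is the 1 specimen whose title carries another date (day 30 in place of 24), so a batch cannot be told apart from the specimen. Libraries also differed by gene length. The slope of expression on length was 0.22 ± 0.16 log2 per doubling in vehicle (SD, n = 3) and 0.21 ± 0.10 in the combination. It was -0.15 ± 0.29 in the BTK inhibitor group and -0.28 ± 0.16 in the PI3K inhibitor group. Within the BTK inhibitor group replicate 6 alone had a positive slope, at 0.18 against -0.28 for replicate 4 and -0.35 for replicate 5. Y-linked transcripts were above 10 CPM in 2 of 3 vehicle specimens and in 1 of 3 specimens of each treated group.

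**Figure D1:**
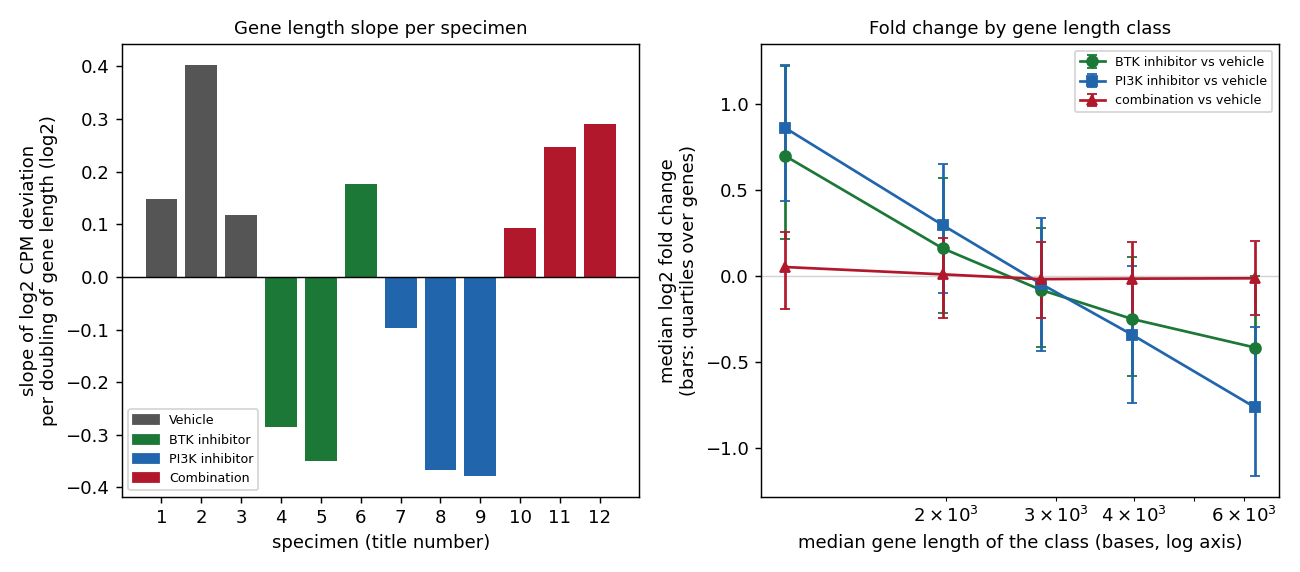
Left, slope of each specimen's log2 CPM deviation on gene length (log2 per doubling), 1 bar per specimen coloured by group. Right, median log2 fold change against vehicle in 5 gene length classes (bases, log axis), with bars from the lower to the upper quartile over genes.

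The transcripts of the drug targets were examined first. Btk was at 100.1 ± 10.4 CPM in vehicle (SD, n = 3) and 96.4 ± 11.6 with the BTK inhibitor. It was at 104.8 ± 2.23 CPM with the PI3K inhibitor and 90.2 ± 3.94 with the combination, and passed in no comparison. Pik3cd, which encodes the delta catalytic subunit, fell from 222 ± 27.0 to 112 ± 17.4 CPM with the PI3K inhibitor (log2 -0.99 ± 0.23 SE, adjusted p = 0.0403 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). This call ended with a gene length offset (log2 -0.39, adjusted p = 0.267 by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and with Y-linked presence as a covariate (-0.99, 0.0699). It also ended without vehicle replicate 1 (0.116), 2 (0.133) or 3 (0.0582), PI3K inhibitor replicate 8 (0.11) or 9 (0.209), or combination replicate 10 (0.0567), 11 (0.0631) or 12 (0.0657), with log2 values from -1.06 to -0.87. Pik3cd was at 149 ± 23.8 CPM with the BTK inhibitor and 164 ± 16.2 with the combination. Ptpn11 was at 110.1 ± 29.3 CPM in vehicle and at 61.2 ± 39.6, 68.1 ± 8.45 and 102.5 ± 11.2 in the BTK inhibitor, PI3K inhibitor and combination groups, and did not pass in any comparison. Without replicate 5 the log2 difference of Ptpn11 between the BTK inhibitor and vehicle went from -0.84 to -0.44, and without replicate 6 to -1.39.

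The comparison of the BTK inhibitor with vehicle asks which transcripts differ when BTK alone is inhibited. Interferon-stimulated genes, the antiviral effectors induced by interferon receptors, were lower as a list, with a median log2 difference of -0.92 and 26 of 28 members negative. Limma camera gave an adjusted p = 4.35e-06, and an adjusted p = 0.812 with an estimated correlation. Their 2 members with the smallest p were Oasl2, at 44.7 ± 25.9 against 121 ± 24.0 CPM (SD, n = 3), and Irf7, at 43.95 ± 12.8 against 90.1 ± 17.7 CPM. Markers of B-lineage precursors were higher as a list (median 0.76 over 18 members, camera adjusted p = 0.000974, and adjusted p = 0.812 with an estimated correlation). Among them were Vpreb1, a surrogate light chain gene, at 52.1 ± 53.2 against 9.11 ± 8.80 CPM, and Sox4 at 64.6 ± 75.9 against 14.8 ± 3.53 CPM. Replicate 5 carried both means: without it the log2 difference went from 2.50 to 1.24 for Vpreb1 (3.65 without vehicle replicate 3) and from 2.11 to 0.50 for Sox4. Nuclear genes of oxidative phosphorylation and DNA replication genes were also higher as lists (medians 0.70 and 0.35, camera adjusted p = 1.39e-05 and 0.000871). Class I PI3K, AKT and mTOR components were lower (median -0.67, camera adjusted p = 0.000871). With an estimated correlation each of these 3 lists had an adjusted p = 0.812.

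Single genes did not pass between the BTK inhibitor and vehicle. Calls were 0 of 12742 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 3153 genes at an unadjusted p under 0.05, 1085 calls by DESeq2 and 2950 by limma voom. Adjusted over the list alone, 4 interferon-stimulated genes were lower and 1 higher. By that adjustment 15 of 30 oxidative phosphorylation genes and 8 of 18 B-lineage precursor genes were higher. Of the PI3K pathway genes 1 of 24 was lower, while 0 of 30 replication genes passed. The gene with the smallest p was Capn11, a calpain protease gene on chromosome 17 (mm10, 45630204 to 45659309). It had no count in the vehicle libraries and 2.43 ± 1.59 CPM with the BTK inhibitor. That was at least 56.8-fold higher against a floor of 3 counts over the vehicle group (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0773). The bound was 36.8-fold without BTK inhibitor replicate 4 and between 36.9-fold and 38.6-fold without any one of vehicle replicates 1, 2 and 3. Ly6d, a surface protein of lymphoid progenitors and B cells, was at 91.5 ± 40.03 against 28.4 ± 2.08 CPM. Socs3, a feedback inhibitor of cytokine signalling, was at 7.43 ± 3.01 against 21.5 ± 3.50 CPM, and C3ar1, the complement C3a receptor, at 1.93 ± 1.38 against 9.20 ± 2.43 CPM. Without BTK inhibitor replicate 6, which leaves libraries of 1 date and BTK inhibitor libraries of negative length slope, there were 3809 calls. Without replicate 5 there was 1. Without replicate 6 the B-lineage list was no longer called (median 0.51, camera adjusted p = 0.235). Without vehicle replicate 1 the replication list was not called (0.24, 0.0611). With a gene length offset the oxidative phosphorylation list had a median of 0.19 and the PI3K pathway list one of -0.17, and neither was called (adjusted p = 0.167 and 0.0508).

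The PI3K inhibitor was compared with vehicle to ask the same of the delta isoform. DNA replication genes rose as a list, with a median log2 difference of 0.76 and 11 of 30 members higher past the threshold. Among these were the thymidine kinase gene Tk1, at 246 ± 60.8 against 102.9 ± 13.1 CPM (SD, n = 3), and the clamp loader genes Rfc3 and Rfc4. The list had a camera adjusted p = 2.16e-06, and an adjusted p = 0.59 with an estimated correlation. Heme synthesis genes and erythroid markers rose too (medians 0.79 and 0.86, with 5 of 20 and 4 of 19 members higher), with adjusted p = 0.59 and adjusted p = 0.726 with an estimated correlation. Uros, an enzyme of heme synthesis, went from 30.7 ± 9.27 to 120.6 ± 56.3 CPM. Gata1, the erythroid transcription factor, went from 47.0 ± 17.8 to 152 ± 52.5 CPM. Interferon-stimulated genes fell, with a median of -0.93 and 7 of 28 members lower, including Oas2, Oas3, Oasl2 and Ddx58 (adjusted p = 0.59 with an estimated correlation). Monocyte markers fell with a median of -0.50 and 4 of 18 members lower (adjusted p = 0.59 with an estimated correlation). Ace was at 4.04 ± 1.43 against 20.8 ± 5.22 CPM and the fractalkine receptor gene Cx3cr1 at 25.4 ± 5.55 against 54.6 ± 7.51 CPM.

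Further lists moved between the PI3K inhibitor and vehicle. Oxidative phosphorylation genes rose (median 1.01, 9 of 30 members higher), including Cox5b and Ndufb9 (adjusted p = 0.59 with an estimated correlation). Components of the B-cell receptor and BTK pathway fell (median -0.74, 6 of 26 members lower), among them Nfatc1, Malt1 and the lipid phosphatase gene Inpp5d (adjusted p = 0.59 with an estimated correlation). Class I PI3K, AKT and mTOR components fell (median -0.97, 5 of 24 members lower), with Pik3r5 at 34.9 ± 4.93 against 77.5 ± 3.87 CPM (adjusted p = 0.59 with an estimated correlation). Sterol and fatty acid synthesis genes fell (median -0.33, 3 of 25 members lower), with the fatty acid synthase gene Fasn at 18.0 ± 5.40 against 75.4 ± 41.3 CPM (adjusted p = 0.734 with an estimated correlation). These 9 lists were the ones called by camera, with adjusted p from 3.85e-08 to 0.0329. Adjusted over the list alone, passing members numbered 18 for replication, 20 for oxidative phosphorylation, 14 for interferon-stimulated genes, 13 lower and 1 higher for PI3K components. They numbered 11 for the B-cell receptor pathway, and 6 each for heme synthesis, erythroid, monocyte and sterol genes.

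Among single genes, 617 rose and 742 fell with the PI3K inhibitor by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.0388. Cbl, a ubiquitin ligase that restrains receptor signalling (chromosome 9, 44149262 to 44234046), had the largest drop under the rule for named genes, from 106 ± 49.6 to 8.29 ± 4.11 CPM (log2 -3.67 ± 0.72 SE, adjusted p = 0.0388 by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Lyst, a lysosomal trafficking gene, went from 255 ± 90.4 to 31.0 ± 21.2 CPM. The fibronectin gene Fn1 went from 661 ± 322 to 103.5 ± 61.9 CPM and the proteoglycan gene Vcan from 35.5 ± 13.1 to 4.66 ± 3.05 CPM. Without PI3K inhibitor replicate 7 the log2 values were -3.73 for Lyst, -3.27 for Fn1 and -3.58 for Vcan, against -3.04, -2.67 and -2.91 with it. Mgat5, Slfn9, Lmbrd2, Xylt1, Abca13 and Slco4c1 also fell, by log2 values between -3.06 and -2.68. Without replicate 7 these were -3.97 for Slfn9, -3.93 for Lmbrd2 and -3.37 for Slco4c1. On the other side, Sparc, a secreted matrix protein gene (chromosome 11, 55394159 to 55420080), rose from 1.83 ± 0.17 to 10.1 ± 4.14 CPM, and the peroxiredoxin gene Prdx2 from 323 ± 115 to 1610.0 ± 770.2 CPM. The heme-binding protein gene Hebp1 rose from 43.5 ± 15.6 to 240.4 ± 90.5 CPM and Cela1, an elastase gene, from 8.60 ± 2.00 to 46.7 ± 28.0 CPM. Mgst3, Pdzk1ip1, Fn3k, Rec114, Cd59a and Asb17os rose by log2 values between 2.29 and 3.15, with 2.95 for Fn3k without vehicle replicate 2 and 3.22 for Rec114 without vehicle replicate 3. Asb17os is an antisense gene that an unstranded library cannot separate from its partner. None of these calls held with the length offset over all specimens, with the Y-linked covariate, or without any one of the 8 specimens listed next.

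Genes higher with the PI3K inhibitor had a median length of 1321 bases and those lower one of 5924.5 bases, against 2835 bases over the tested genes. With a gene length offset 0 genes were called by edgeR (2785 at an unadjusted p under 0.05). With the offset and without BTK inhibitor replicate 5 there were 2364 calls, which held 754 of the 1359 genes called without the offset. With the offset over all specimens the median size of the change of these 1359 genes went from 1.33 to 0.69. The PI3K pathway list, whose median then went from -0.97 to -0.27, was not called (camera adjusted p = 0.127). The sterol list was not called either (0.0762), although its median of -0.29 stayed near the -0.33 without the offset. Calls were also 0 without any one of vehicle replicates 1, 2 and 3, PI3K inhibitor replicates 8 and 9 and combination replicates 10, 11 and 12. They numbered 4375 without BTK inhibitor replicate 5, 3392 without replicate 6, 1901 without PI3K inhibitor replicate 7, 3221 by DESeq2 and 4761 by limma voom. Without vehicle replicate 1 the erythroid list had a median of 0.33 (camera adjusted p = 0.128) and the monocyte list one of -0.41 (0.0554). The sterol list was not called without vehicle replicate 2 (-0.25, 0.0691) or PI3K inhibitor replicate 7 (-0.38, 0.103), nor with the Y-linked covariate (-0.24, 0.0952).

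The combination was compared with vehicle to ask what both inhibitors together change. Erythroid markers were higher as a list, with a median log2 difference of 1.32 and 19 of 19 members positive (camera, adjusted p = 5.61e-18, and adjusted p = 0.168 with an estimated correlation). The erythropoietin receptor gene Epor stood at 56.98 ± 9.14 against 25.4 ± 12.7 CPM (SD, n = 3). Heme synthesis genes were higher (median 0.96, adjusted p = 8.86e-08 by camera), with Uros at 82.3 ± 18.2 against 30.7 ± 9.27 CPM (adjusted p = 0.168 with an estimated correlation). Interferon-stimulated genes were lower, with 28 of 28 members negative, a median of -0.94 and a camera adjusted p = 4.1e-22 (adjusted p = 0.168 with an estimated correlation). Ifit3b stood at 2.66 ± 0.43 against 10.7 ± 2.57 CPM and the nucleic acid sensor gene Zbp1 at 14.0 ± 3.37 against 34.9 ± 11.2 CPM. DNA replication genes were higher, 30 of 30 positive with a median of 0.52 (camera adjusted p = 1.83e-13), and mitosis genes were higher with a median of 0.25 and 28 of 28 positive (0.000675). These 2 lists had an adjusted p = 0.168 and an adjusted p = 0.219 with an estimated correlation.

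Markers of neutrophils, granulocyte-monocyte precursors and monocytes were lower as lists in the combination group. Medians were -0.50 for mature neutrophils, -0.57 for immature neutrophils, -0.41 for granulocyte-monocyte precursors and -0.37 for monocytes, with camera adjusted p of 5.31e-07, 2.3e-06, 7.75e-05 and 2.07e-05. In the same order they had adjusted p = 0.219, 0.205, 0.281 and 0.168 with an estimated correlation. Macrophage, dendritic cell and eosinophil, basophil and mast cell lists were not called. Their mean log2 CPM was taken relative to all specimens. It went from 0.263 in vehicle to -0.03 for macrophages, from -0.164 to 0.066 for dendritic cells and from -0.124 to -0.25 for the last. Cxcr2, the neutrophil chemokine receptor gene, was at 277 ± 46.7 against 436 ± 26.3 CPM. The secondary granule gene Lcn2 was at 3014 ± 320.5 against 5095 ± 804.4 CPM, and the endotoxin co-receptor gene Cd14 at 11.8 ± 1.35 against 24.9 ± 10.2 CPM. Glycolysis genes (median -0.40), inflammatory cytokine and receptor genes (-0.37), NF-kB targets (-0.28) and unfolded protein response genes (-0.21) were lower as well, with camera adjusted p of 3e-04, 0.00165, 0.00605 and 0.0417. These had adjusted p = 0.281, 0.219, 0.281 and 0.354 with an estimated correlation. Mature B cell markers were higher (median 0.49, camera adjusted p = 0.00122), with Ms4a1, which encodes CD20, at 25.7 ± 12.1 against 6.99 ± 0.55 CPM (adjusted p = 0.281 with an estimated correlation). Stroma and endothelium markers were higher (median 0.64, camera adjusted p = 0.000145, and adjusted p = 0.168 with an estimated correlation), and the collagen genes Col1a1 and Col1a2 stood at 47.0 ± 38.3 and 36.2 ± 25.8 against 4.82 ± 3.36 and 3.06 ± 2.09 CPM. Without combination replicate 11, at 91.1 and 65.8 CPM, their log2 differences went from 3.28 and 3.56 to 2.37 and 2.81, and without vehicle replicate 2 to 4.01 and 4.29 for Col1a1 and Col1a2. Sparc was at 12.95 ± 7.16 against 1.83 ± 0.17 CPM.

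No single gene passed between the combination and vehicle by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 626 genes at an unadjusted p under 0.05, 22 calls by DESeq2 and 1231 by limma voom. Sparc had the smallest p (log2 2.82 ± 0.42 SE, adjusted p = 0.149 in that edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Adjusted over the list alone, 15 of 28 interferon-stimulated genes were lower and 4 of 20 heme synthesis, 3 of 15 stroma and 2 of 16 mature B cell genes were higher, while 0 members of the other 11 lists called passed. Without vehicle replicate 1 the NF-kB, cytokine and unfolded protein response lists were not called (medians -0.18, -0.26 and -0.16, camera adjusted p = 0.185, 0.0578 and 0.178). Nor was the last without combination replicate 11 (-0.11, 0.26). Its median stayed near the -0.21 of the full set without PI3K inhibitor replicate 9 (-0.21, 0.0503), with the length offset (-0.22, 0.0576) and with the Y-linked covariate (-0.21, 0.0766), where the call also ended. Without vehicle replicate 1 the erythroid median was 0.79.

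**Figure D2:**
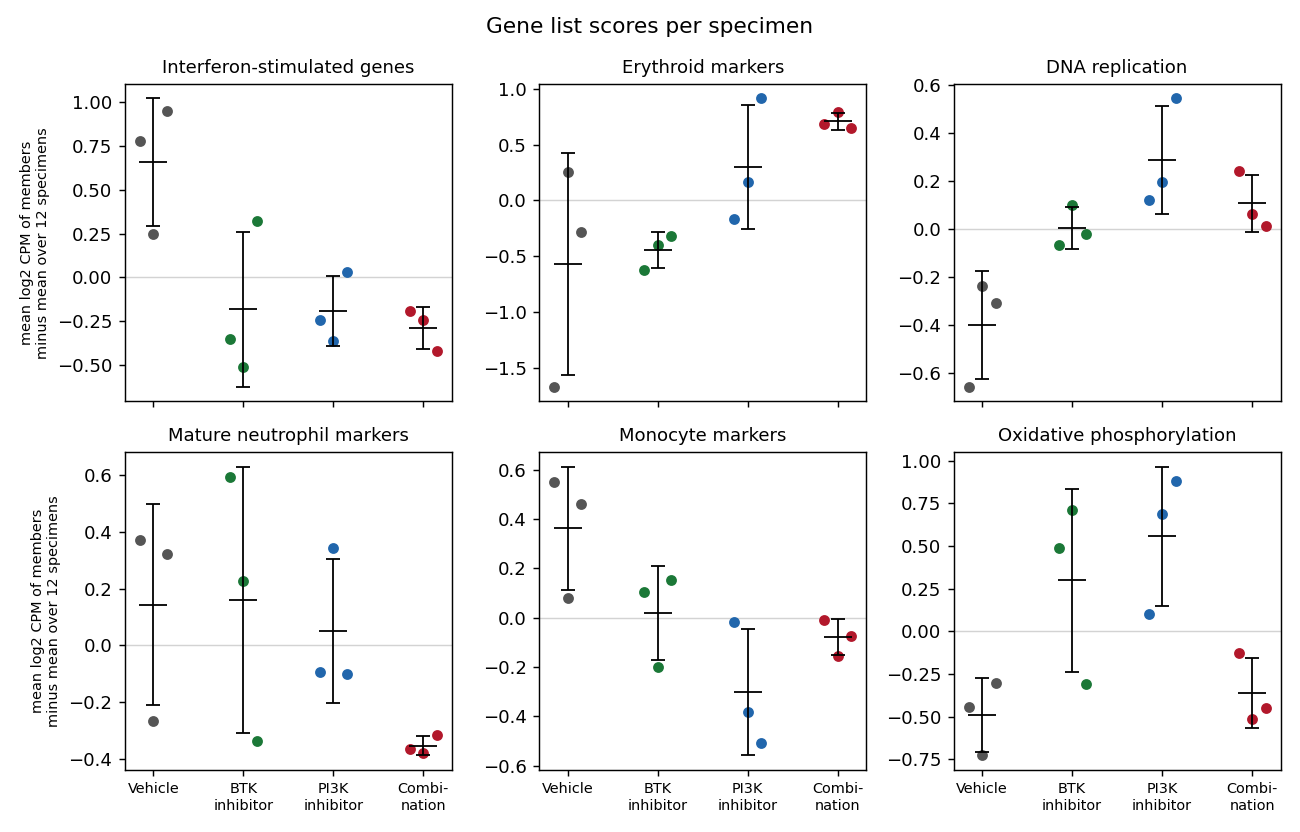
Scores of 6 gene lists in the 12 specimens: each point is 1 specimen's mean log2 CPM over the members minus the mean over all specimens, with the group mean and SD (n = 3) in black. Interferon-stimulated genes scored 0.66 ± 0.36 in vehicle and -0.29 ± 0.12 in the combination, and erythroid markers -0.57 ± 0.99 and 0.71 ± 0.08.

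The combination was set against each single inhibitor to ask what the second drug adds. Against the BTK inhibitor, erythroid markers were higher as a list (median 1.18, camera adjusted p = 6.87e-05), with the nuclear transport gene Xpo7 at 129.8 ± 16.3 against 48.75 ± 16.9 CPM (SD, n = 3). Stroma markers were higher (1.33, adjusted p = 0.000579 by camera), with Col1a2 at 36.2 ± 25.8 against 4.19 ± 3.39 CPM (log2 difference 3.01, and 2.27 without combination replicate 11 and 3.73 without BTK inhibitor replicate 6), as were PI3K pathway components (0.56, 0.00563). Oxidative phosphorylation genes (-0.54, 0.000199), B-lineage precursors (-0.47, 0.00868), mature neutrophils (-0.57, 0.00849), granulocyte-monocyte precursors (-0.46, 0.0382) and eosinophil, basophil and mast cell markers (-0.35, 0.0374) were lower. Each pair of numbers was the median log2 difference and the camera adjusted p. With an estimated correlation all 8 lists had an adjusted p = 0.881. Against the PI3K inhibitor, oxidative phosphorylation genes (-0.88, 1.63e-08), eosinophil, basophil and mast cell markers (-0.65, 0.0194) and granulocyte-monocyte precursors (-0.66, 0.0412) were lower. PI3K pathway (0.68, 0.000781) and B-cell receptor pathway components (0.66, 0.0223) were higher, each of the 5 with an adjusted p = 0.94 with an estimated correlation. Interferon-stimulated genes had medians of -0.04 and -0.07 in these comparisons and were called in neither.

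Single genes again did not pass in either of these comparisons. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment there were 0 calls against each single inhibitor, with 2569 genes at an unadjusted p under 0.05 against the BTK inhibitor and 3660 against the PI3K inhibitor. Calls were 577 and 1226 by DESeq2 and 4973 and 5331 by limma voom. Adjusted over the list alone against the BTK inhibitor, 8 of 19 erythroid and 4 of 15 stroma genes were higher. By that adjustment 10 of 30 oxidative phosphorylation, 5 of 18 mature neutrophil, 4 of 18 B-lineage and 2 of 18 eosinophil, basophil and mast cell genes were lower, while 0 of 14 precursor and 0 of 24 PI3K pathway genes passed. Against the PI3K inhibitor the counts were 19 lower of 30 oxidative phosphorylation, 7 lower of 18 eosinophil, basophil and mast cell genes. They were 2 higher of 26 B-cell receptor pathway, 1 higher of 24 PI3K pathway and 0 of 14 precursor genes. Tet2, a DNA demethylase gene, was at 29.2 ± 9.92 CPM with the combination against 9.79 ± 1.59 with the PI3K inhibitor. The lysozyme gene Lyz1, which shares sequence with Lyz2, was at 5.80 ± 1.36 against 21.2 ± 10.1 CPM. With a length offset the oxidative phosphorylation, PI3K pathway, mature neutrophil, precursor and eosinophil lists were not called against the BTK inhibitor (medians from -0.20 to 0.18, camera adjusted p from 0.438 to 0.794). Nor were the PI3K pathway, B-cell receptor pathway, precursor and eosinophil lists called against the PI3K inhibitor (medians from -0.12 to 0.25, adjusted p from 0.0758 to 0.901). With a mean CPM of at least 5 the stroma (median 0.77, 0.0537), precursor (-0.46, 0.0545) and eosinophil lists (-0.26, 0.0571) were not called against the BTK inhibitor. Nor were the precursor (-0.64, 0.0771), eosinophil (-0.39, 0.0587) and B-cell receptor pathway lists (0.48, 0.0799) against the PI3K inhibitor. Calls were 3470 against the BTK inhibitor without its replicate 6, the specimen of another date and the 1 positive length slope of its group. Against the PI3K inhibitor they were 2499 without replicate 5 and 1798 without replicate 6. The lists below lost their calls on leaving out 1 specimen, with the median and the adjusted p then reached in brackets. The B-lineage call ended without BTK inhibitor replicate 6 (-0.26, 0.473). Without replicate 4 the precursor (-0.18, 0.42), neutrophil (-0.41, 0.204), eosinophil (-0.25, 0.191) and PI3K pathway calls (0.53, 0.055) against the BTK inhibitor ended. The B-cell receptor pathway call ended without PI3K inhibitor replicate 9 (0.45, 0.0689). Against the BTK inhibitor the precursor call also ended without replicate 6 (-0.61, 0.0774), 11 (-0.39, 0.0742) or 12 (-0.42, 0.0671), and the eosinophil call without replicate 6 (-0.34, 0.169) or 11 (-0.24, 0.156). Against the PI3K inhibitor the precursor call ended without replicate 2 (-0.66, 0.0562), 5 (-0.66, 0.0514), 7 (-0.69, 0.0984), 8 (-0.46, 0.169), 11 (-0.61, 0.0734) or 12 (-0.59, 0.0698). The eosinophil call ended there without replicate 7 (-0.59, 0.0835), 8 (-0.48, 0.0619) or 11 (-0.56, 0.0646).

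The single inhibitors were also set against each other. Carbonic anhydrase genes of red cell precursors stood higher with the PI3K inhibitor, Car1 at 697 ± 331 against 269 ± 121 CPM and Car2 at 1496 ± 569.6 against 721 ± 90.6 CPM (SD, n = 3). Cx3cr1 stood at 25.4 ± 5.55 against 53.6 ± 23.9 CPM, and none of the 3 passed. The log2 difference of Cx3cr1 went from -1.07 to -0.67 without BTK inhibitor replicate 5. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes were called (791 at an unadjusted p under 0.05), as by DESeq2 and limma voom. A test for any difference among the 4 groups called 0 genes by edgeR (3903 at an unadjusted p under 0.05), 3140 by DESeq2 and 6695 by limma voom. By edgeR it called 4115 without BTK inhibitor replicate 6, the specimen of another date and the 1 positive length slope of its group. Without replicate 5 it called 1387. The interaction, which asks whether the combination departs from the sum of the single effects on the log2 scale, called 3522 genes by edgeR, of which 1530 were higher and 1992 lower than that sum. Higher ones had a median length of 5490.0 bases and lower ones one of 1275.5 bases. Of the genes called 1177 of the 3522 were also called between the PI3K inhibitor and vehicle. The interaction holds that comparison with reversed sign on the same libraries, so part of this overlap is built in. With a gene length offset 1 gene was called. Interaction calls were 0 without combination replicate 11 or 12, 1 without vehicle replicate 2 or PI3K inhibitor replicate 8 or 9, 2246 without vehicle replicate 1, 2167 without BTK inhibitor replicate 4 and 5692 without replicate 6.

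Fold changes of the comparisons with vehicle were related across genes, which are not independent replicates, and they share the vehicle libraries. The correlation was 0.837 between the BTK and PI3K inhibitors, 0.392 between the BTK inhibitor and the combination, and 0.498 between the PI3K inhibitor and the combination. Means were 0.472, 0.471 and 0.474 when residuals of whole specimens were regrouped with no effect (central 95% range -0.413 to 0.905 for the first). Covariances were 0.538, 0.13 and 0.178 against simulated values of 0.116, 0.113 and 0.115, the first above its simulated range of -0.0672 to 0.377. The share of genes with the same sign was 82.8%, 63.7% and 67.0% against simulated shares of 67.0%, 66.9% and 67.2%, each within its simulated range (30.9% to 87.9% for the first). No call was shared because 1 comparison alone had any. The regrouped residuals came from specimens of every group, so the simulated values hold the shared part of a mixed group. That need not be the part of the 3 vehicle libraries, because the spread differed between groups. Chi-square per degree of freedom between specimens was 30.3 to 132.3 within vehicle and 194.8 to 633.1 within the BTK inhibitor group. It was 83.4 to 116 within the PI3K inhibitor group and 20.5 to 45.3 within the combination. The simulated values therefore cannot tell how much of each covariance came from the shared vehicle libraries. The 3 vehicle libraries cannot be divided into 2 groups of 2 to measure their part directly. Fold changes against vehicle also fell with gene length across genes for the BTK and PI3K inhibitors (Spearman rho -0.503 and -0.642, and -0.041 for the combination). The part of this length trend in the excess was not tested.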

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

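The tests of explanations below, including the gene length offset and the Y-linked covariate, were all chosen after the results were seen, and the limits for reading the length offset, the Y-linked covariate and the share of myeloid cells were changed after their values were seen. The interaction was called for 3522 genes by edgeR, and 353 of them were still called with the length offset and without BTK inhibitor replicate 5, where the median size of the interaction went from 1.93 to 0.65. Calls were 1 with the offset over all specimens, 0 without combination replicate 11 or 12 and 1 without vehicle replicate 2 or PI3K inhibitor replicate 8 or 9. Whether the inhibitors or the libraries differ in these genes was left open. Under the rule for named genes the log2 interaction was 4.88 for Cbl, 4.23 for Mgat5, 4.17 for Lyst, 4.16 for Ago2, 4.06 for Vcan, 4.05 for Med12, 3.98 for Pira2, 3.97 for Abca13, 3.91 for Pdpr and 3.91 for Slfn9. On the lower side it was -6.17 for Rn45s, -5.16 for Myeov2, -4.95 for Snhg8, -4.76 for Rplp2, -4.72 for Tmem256, -4.70 for Rpl38, -4.69 for Snhg7, -4.68 for Chchd2, -4.64 for Ndufa2 and -4.63 for Atp5e, and Pik3cd had an interaction of 1.13 (0.07 with the length offset). BTK inhibitor replicate 5 carried much of the lower values: without it the log2 interaction was -1.59 for Rn45s, which was then not called (adjusted p = 0.151 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without it the values were -2.99 for Myeov2, -2.59 for Snhg8, -2.64 for Rplp2, -2.55 for Tmem256, -2.63 for Rpl38, -2.39 for Snhg7, -2.44 for Chchd2, -2.75 for Ndufa2 and -2.61 for Atp5e, and these 9 and the 10 higher genes were still called. Without BTK inhibitor replicate 6 the higher values grew, to 6.11 for Cbl, 6.58 for Mgat5, 5.07 for Lyst, 6.14 for Ago2, 5.51 for Med12, 5.54 for Pira2, 5.21 for Abca13, 6.35 for Pdpr and 5.50 for Slfn9, as did that of Vcan without PI3K inhibitor replicate 7 (4.75) and the size for Rn45s without combination replicate 10 (-7.04). Of 50 groupings of the 12 specimens, 1 gave as many interaction genes, the real one, and the highest other gave 2177. A share of 1 in 50 is the smallest that these groupings can give. Since the count also fell to 0 or 1 without some single specimens, chance is not set aside.

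The first pattern is the length trend of the calls between the PI3K inhibitor and vehicle. An effect of the PI3K inhibitor wherever it was given is argued against by the combination, whose length slopes lay above those of the PI3K inhibitor group by 0.491 on average, with no overlap of specimens. The combination also held the BTK inhibitor. Its slopes therefore cannot weigh against an effect of the PI3K inhibitor given alone, or one that library quality hides. Library quality stays open: the slope fell with the share of Rn45s over the 12 specimens (Spearman rho = -0.797, permutation p = 0.00301, and Pearson r = -0.636 on log10 share, permutation p = 0.00431), with r = -0.753 without replicate 5 and -0.678 within groups, the 1 such relation computed. Replicate 10, with the next highest share, had a slope of 0.09 against the relation, so r = -0.924 without both adds no support. Whether the trend is the whole cause cannot be told apart from a treatment effect, since the offset over all specimens ended every call (median change 0.69 with a median SE of 0.257, against 1.33 and 0.344) while without replicate 5 it left 754 of the 1359 genes called.

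The second pattern is the lower expression of interferon-stimulated genes in the 9 treated specimens, whose score was lower than in vehicle by -0.875 (exact permutation over 220 splits, two-sided p = 0.00909). This list was picked from the 34 after its calls in these same specimens were seen. The permutation p is not adjusted for that choice and adds no separate support. A length trend as the whole cause is argued against by medians of -0.944 for the PI3K inhibitor and -0.876 for the BTK inhibitor against vehicle with the offset, where the trend was present, and the mix of male and female specimens by medians of -0.957, -1.048 and -0.995 for the BTK inhibitor, PI3K inhibitor and combination against vehicle with Y-linked presence as a covariate. Fewer monocytes stay open: the difference between the interferon and monocyte scores was -0.392 in treated against vehicle specimens (exact permutation p = 0.0636). An effect of the inhibitors on interferon signalling may also account for the pattern and was not tested apart from these.

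The third pattern is the higher expression of erythroid markers in the combination group. Vehicle replicate 1, which had the lowest erythroid score, is argued against as the whole cause by a median of 0.79 without it, while the length offset, with a median of 1.295, decided nothing because the length slopes of these 2 groups were alike (0.21 and 0.22) and left it no trend to remove. A lower share of myeloid cells, which would raise every other type alike, stays open as the whole cause. The mean score of the 8 other lists outside the myeloid lineage changed by 0.217 (summed SDs 0.202) against 1.28 for erythroid markers. Without vehicle replicate 1 it changed by 0.188 (0.221) against 0.724. These summed SDs leave out the spread of the erythroid score, whose SD was 0.993 in vehicle (n = 3). An earlier measure held this spread. It was the erythroid excess of 1.33 over T cell, NK cell and megakaryocyte scores, and lay within its SDs of 0.305 and 1.11 summed. The changes ran from -0.271 for T cells over -0.005 for megakaryocytes, 0.032 for stem and progenitor cells, 0.12 for NK cells, 0.189 for plasma cells, 0.254 for B-lineage precursors and 0.522 for mature B cells to 0.894 for stroma, with 7 of 8 short of the erythroid change by more than their summed SDs, stroma being the exception, and 4 of 8 without vehicle replicate 1. A change in the erythroid cells themselves may be the source and stays open.

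Other groupings of the specimens were counted for each test. Each comparison of 3 against 3 has 10 splits, too few for a share under 0.05. Between the PI3K inhibitor and vehicle, 1359 genes were called and the highest other split gave 0 (1 of 10 splits as large), and in the other 5 pairwise comparisons the real count and the highest other were both 0 (10 of 10, which a real count of 0 makes certain). For gene lists, the real counts were 5, 9, 15, 8 and 5 for the BTK inhibitor, PI3K inhibitor and combination against vehicle and the combination against the BTK and PI3K inhibitors, the highest other splits gave 16, 18, 18, 10 and 17, and 7, 8, 4, 5 and 10 of 10 splits were as large. The number of lists called therefore did not set the real groups apart from mixed groupings. The cause of the list counts in mixed groupings was not tested. For any difference among the 4 groups the real count was 0, so 50 of 50 groupings had to be as large and the count decides nothing about chance. The highest other grouping gave 3254 genes, but it kept the 3 vehicle and the 3 combination specimens together and so held part of the treatment contrast. The next gave 1711 genes in a grouping that kept no treatment group together. Whether that count came from a structure of the specimens or from chance was not tested.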

How the results depend on the processing

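The length offset, the offset without BTK inhibitor replicate 5, Rn45s left out and the Y-linked covariate were chosen after seeing the data. Of 42 lists called, 867 of 1008 alternative values kept direction and call and 141 lost the call. Apart from the estimated correlation and fry, these alternatives used the same preset correlation, so much of this agreement is built in. With an estimated correlation all 42 calls ended. Of 511 gene values named, 10456 of 12183 alternatives were on the same side of the threshold, 1008 lost and 719 gained a call, and 0 reversed a called direction. Values called in neither fit count as the same side. Every pairwise comparison but the PI3K inhibitor against vehicle had 0 calls, so this share does not measure how well calls held. The cause of the changes below was not tested unless stated.

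Without a filter on low counts, the BTK inhibitor and combination against vehicle, the combination against the BTK inhibitor and any difference had 1 call each. DESeq2 called 1085, 3221 and 22 genes for the BTK inhibitor, PI3K inhibitor and combination against vehicle, 577 and 1226 for the combination against the BTK and PI3K inhibitors, and 3140 for any difference. Limma voom called 2950, 4761, 1231, 4973, 5331 and 6695 in that order and 6729 for the interaction. With only the groups compared, which fits fewer specimens, 4057 genes were called for the PI3K inhibitor against vehicle and 4004 for the combination against the PI3K inhibitor. The length offset gave 0 for the PI3K inhibitor against vehicle and 1 for the interaction, and 16 lists for the PI3K inhibitor against vehicle, 4 for the combination against the BTK inhibitor and 3 against the PI3K inhibitor. Without BTK inhibitor replicate 5 as well, it gave 1, 2364 and 3 genes against vehicle, 1 for the combination against the BTK inhibitor, 489 for the interaction and 2 for any difference, and 12, 18, 15 and 2 lists for the BTK and PI3K inhibitors against vehicle and the combination against the BTK and PI3K inhibitors. With the Y-linked covariate 0 genes were called for the PI3K inhibitor against vehicle. With an estimated correlation 0 lists were called in all 5 comparisons, and by fry 0 in all but the PI3K inhibitor against vehicle, where there were 6. A mean CPM of at least 5 left 5 and 2 lists for the combination against the BTK and PI3K inhibitors. Other scaling factors moved the median of all genes most in the interaction, where it dropped by 0.0337 log2 with DESeq2 size factors.

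Leaving out 1 specimen at a time gave 0 to 3809 genes for the BTK inhibitor against vehicle, 0 to 4375 for the PI3K inhibitor, 0 to 0 for the combination, 0 to 3470 and 0 to 2499 for the combination against the BTK and PI3K inhibitors, 0 to 1 between the inhibitors, 0 to 5692 for the interaction and 0 to 4115 for any difference. List counts ranged from 4 to 11, 8 to 12 and 14 to 20 against vehicle, and 4 to 14 and 3 to 6 for the combination against the BTK and PI3K inhibitors. The high counts came without BTK inhibitor replicate 6, the 1 specimen with another date in its title (3809, 3470, 5692 and 4115), or 5 (4375 and 2499). Replicate 6 was also the 1 BTK inhibitor library with a positive length slope (0.18, against -0.28 for replicate 4 and -0.35 for 5). For the counts without it, the date cannot be told apart from the length trend. Interaction calls fell to 0 without combination replicate 11 or 12 and to 1 without vehicle replicate 2 or PI3K inhibitor replicate 8 or 9. The interferon-stimulated list was called in 12 of 12 such fits in each comparison with vehicle. Fits that left out a specimen of a group not compared kept the same compared libraries, so they could hardly lose the call. All 12 used the preset correlation, and with an estimated correlation the list was called in no comparison. Treating the 24 samples separately, or using either sample of a specimen alone, was not run because the table holds 1 column per specimen. No paired analysis was possible because the groups share no replicate number. Depth limits BTK inhibitor replicate 5 most, at 8993950 counts.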

Other observations

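Sparc averaged 1.83 ± 0.17 CPM in vehicle, 5.25 ± 1.23 with the BTK inhibitor, 10.1 ± 4.14 with the PI3K inhibitor and 12.95 ± 7.16 with the combination (SD, n = 3), and Adam33, a metalloprotease gene of mesenchymal cells, stood at 2.89 ± 1.24 CPM with the combination against 0.229 ± 0.165 in vehicle. Sparc passed with the PI3K inhibitor against vehicle and not with the combination, where Adam33 did not pass either, and the calls of Sparc and of Adipoq below with the PI3K inhibitor ended with a gene length offset and without any one of vehicle replicates 1, 2 and 3, PI3K inhibitor replicates 8 and 9 and combination replicates 10, 11 and 12, and that of Adipoq also without BTK inhibitor replicate 4. The adiponectin gene Adipoq, an adipocyte and marrow stroma marker, was at 0.999 ± 0.241 CPM with the PI3K inhibitor against 0.330 ± 0.063 in vehicle, where it passed, and at 0.150 ± 0.131 with the BTK inhibitor. These Adipoq values rest on few counts. Vehicle specimens had 9, 7 and 7 counts and PI3K inhibitor specimens 17, 17 and 18. BTK inhibitor specimens had 4, 0 and 6. Capn11 had no count in the vehicle libraries and 1 count over the combination group, against 2.43 ± 1.59 CPM with the BTK inhibitor and 1.23 ± 0.61 with the PI3K inhibitor, the latter at least 28.7-fold above the vehicle floor of 3 counts over the group (18.6-fold without vehicle replicate 2, 19.2-fold without 3 and 19.5-fold without 1).

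The acute phase gene Orm1 was at 17.8 ± 7.86 CPM with the combination against 53.4 ± 9.92 with the PI3K inhibitor, and Wfdc21, a secreted protein gene, at 291 ± 58.7 against 1177 ± 769.8 with the BTK inhibitor, neither past the threshold. Mki67 and Tk1 stood opposite ways between the combination and the PI3K inhibitor, neither past the threshold: the proliferation marker Mki67, with 10075 bases, was at 999.7 ± 249.8 against 320.5 ± 21.6 CPM, while the replication gene Tk1, with 1369 bases, was at 149.7 ± 23.2 against 246 ± 60.8 CPM.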
